A study of Mus musculus with 6 samples.

How the data were processed

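RNA was sequenced from mouse bone marrow-derived macrophages after treatment with oxLDL, with 3 libraries from LDL receptor knockout cells (LKO) and 3 from ALDH2 and LDL receptor double knockout cells (DKO). Samples were grouped by their labels. The processed files hold, per the file headers, an expected count, an FPKM value and a transcript length for each gene, with NCBI gene numbers and RefSeq transcript accessions. Expected counts are the authors' estimates of reads per gene, not scaled to depth, and between 23.2% and 23.6% of the listed genes of a library had a fractional value (further than 0.005 from a whole number), which arises where reads are divided among genes. FPKM values are the deposited expected counts scaled to transcript length and library size by the authors, per the file headers. Bowtie 0.12.2 and the genome build mm8 are named in the submitters' processing notes. The counting tool, the read length and the strand setting are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. Each file lists only genes with an FPKM of at least 0.01, and a gene missing from a file was taken as 0 there.

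Gene symbols came from a RefSeq gene table of assembly GRCm38, used only for names and for which genes neighbour each other, because it is not the build of the files. Of 16871 gene numbers, 16832 matched a symbol. The other 39 took at most 0.0448% of the counts of a library and stayed in the tests. No coordinates are printed for the same reason.

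Depth was between 10760625 and 10987584 expected counts per library, and the biological coefficient of variation within groups was 0.0413. Replicates were compared before averaging: over genes with at least 20 reads in a pair, the chi-square per degree of freedom was between 1.68 and 3.71 within groups and between 8.30 and 14.9 across groups, so each library was counted as its own sample. Fold bounds against a group at 0 use a floor of 3 counts per library and cover counting error only, as sequencing duplicates are not separate molecules.

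Before the data were examined, the design, the alternatives, the gene lists and the rule for naming genes were fixed. The design foresaw FPKM as the only unit with limma as its test, and edgeR if counts were present; since expected counts were present, edgeR was the main test. Expected counts were rounded to whole numbers and tested in R 4.3.3 with the edgeR 4.0.16 quasi-likelihood test (filterByExpr, TMM normalization, no block), with Benjamini-Hochberg adjustment over 11809 genes and a threshold of 0.05. Standard errors were derived from the fold change and the F statistic. Means ± SD are of the deposited FPKM values over 3 libraries. Aldh2 was also tested by an exact two-sided permutation test.

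The lists were 36, of which 34 had at least 5 tested members. They cover lysosome, lipoprotein uptake, cholesterol and fatty acid handling, AMPK, histone deacetylases, aldehyde metabolism, oxidative stress, inflammation, interferon, antigen presentation, macrophage identity and activation, cell cycle, stress, other marrow cell types and technical signs. The mast cell and basophil list and the mitochondrially encoded genes had too few tested members. Of 960 listed names, 894 were found in the files, 24 of them as an older name. The lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 34 lists, and again with an estimated correlation, on ranks, and with fry. Fry's directional test called 20 lists and its mixed test, which asks for change in either direction, called 34.

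The genes named are the targeted gene Aldh2, then the 8 largest rises and the 8 largest falls among genes that passed, with a mean CPM of at least 2 in a group and no overlap between groups. In addition come up to 4 members of smallest p of each list described, and Atp6v0e2, Hdac3, Prkaa1, Cd36, Abca1, Abcg1, Lipa and Npc1. Where 5 or fewer members of a list went in a direction, those outside this rule are named too, chosen after their values were seen. Some genes that the rule takes are not reported here.

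Alternatives were DESeq2 1.42.0, edgeR with DESeq2 size factors, edgeR without a count filter, a replicate block, and limma on log2(FPKM + 1) for genes with an FPKM of at least 1 in at least 3 libraries. The limma fit was repeated with pseudocounts of 0.1 and 5, without a filter, with an FPKM minimum of 5, after rescaling to TPM, quantile normalization or median centring, without a variance trend and with array weights. Fold changes from limma are on the log2(FPKM + pseudocount) scale, which understates the change of low genes. Each replicate was left out in turn, and stricter thresholds were applied. On counts simulated from the DKO against LKO comparison (200 changed genes, 11708 genes tested), edgeR recovered 70% of genes changed 1.25-fold, 90% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, with 2.72% false calls. DESeq2 recovered 58%, 88%, 94% and 100% with 1.16% false calls on the same genes, and limma 52%, 86%, 94% and 96% with 5.20% false calls on 10563 genes. The changed genes were drawn only from well-counted genes, and the simulated spread followed the fitted trend without scatter from gene to gene. These shares hold for such genes only. In simulated lists, the list shifted by 1.3-fold was called and 0 of the unshifted lists were. The simulated genes varied independently of each other, unlike members of some real lists (estimated correlation 0.503 in the interferon list). The simulation therefore cannot tell how often the preset correlation of 0.01 gives false calls in such lists.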

Results

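Gene expression was measured by RNA sequencing in bone marrow-derived macrophages, which are macrophages grown from mouse marrow cells in culture. The marrow came from C57BL/6 mice aged 8 weeks. The cells were cultured for 7 days and then given oxidised low-density lipoprotein (oxLDL), a modified lipoprotein that macrophages take up in atherosclerotic plaques. There were 3 libraries from LDL receptor knockout cells, which served as the control (LKO), and 3 from cells lacking both the LDL receptor and the mitochondrial aldehyde dehydrogenase ALDH2 (DKO). Each library held between 10760625 and 10987584 expected counts and listed between 14904 and 15048 genes. The 10 most abundant genes took between 8.05% and 8.40% of the counts of a library. The first principal component carried 49.9% of the variance and separated LKO from DKO. The labels do not say that the samples came from separate animals, so p-values measure the spread between these samples, which may be technical.

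The comparison asked how gene expression in oxLDL-treated macrophages without the LDL receptor differed when ALDH2 was also missing. The targeted gene, Aldh2 (NCBI gene 11669), stood at 241 ± 6.83 FPKM in LKO and 7.13 ± 0.181 in DKO (SD, n = 3 each), so that 3.11% of the LKO level remained. Its log2 fold change was −5.01 with a standard error of 0.06 (edgeR adjusted p = 4e-24). An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow.

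Of 11809 genes tested, 1689 (14.3%) passed an edgeR adjusted p of 0.05, of which 876 were higher and 813 lower in DKO. Most of these changes were small: 76.4% of the genes that passed differed by less than 1.5-fold, while 71 were at least 2-fold higher and 73 at least 2-fold lower. Limma on log2(FPKM + 1) called 1130 genes, 561 of them higher. In the same libraries, neutrophil markers were lower in DKO (median log2 fold change −0.61) and stromal and fibroblast markers higher (0.70), beside each of the gene groups described.

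The largest rises in DKO were in interferon-induced genes, a proton pump subunit and transcripts annotated as pseudogenes. Ifi44l (NCBI gene 15061), an interferon-induced gene, had no count in any LKO library and 18.5 ± 3.03 FPKM in DKO, at least 153-fold above a floor of 3 counts per library (edgeR adjusted p = 3e-14). Atp6v0e2 (NCBI gene 76252), a subunit of the vacuolar proton pump that acidifies lysosomes, also had no count in LKO and 8.27 ± 0.590 FPKM in DKO, at least 55.1-fold above the same floor (edgeR adjusted p = 1.2e-12). A read of Atp6v0e2 is worth about 0.0496 FPKM, above the lowest value the files list, so its absence from the LKO files means no read counted. Among the 30 tested genes nearest to Atp6v0e2, 5 also changed by at least 1.5-fold, a number at the 98.1th percentile of all such windows. Without the neighbouring Gimap genes it was 3, at the 89.3th percentile. A window of 5 arose somewhere in 992 of 1000 shuffled gene orders, which counts windows at any place and not the one around Atp6v0e2. The highest window, with 8, lay nearby in gene order around Cycs and Hnrnpa2b1, and 7 of the shuffled orders reached 8. The pseudogene Gm8580 was at 0 in LKO and 24.2 ± 2.90 FPKM in DKO (at least 51.1-fold), and the transcribed pseudogene Gm6644 went from 1.10 ± 0.782 to 33.4 ± 1.99. Counts of pseudogenes can be shared with their parent genes and are uncertain. Ifi44 rose from 7.07 ± 1.68 to 62.9 ± 5.60 FPKM (log2 fold change 3.16 ± 0.10 SE). The rise of Ifi44l from 0 lay far above the median fold of the interferon list, 1.47. The window around Ifi44l was not looked at on its own. Linked variants and an effect of ALDH2 loss on Ifi44l cannot be told apart with these libraries. Acacb, which makes the malonyl-CoA that restrains mitochondrial fatty acid entry, rose from 0.053 ± 0.025 to 0.297 ± 0.065 FPKM. Of the 30 tested genes nearest to Acacb, 6 changed by at least 1.5-fold, against 4 around Aldh2 and a median window of 1. Linked variants and an effect of ALDH2 loss on Acacb itself cannot be told apart with these libraries. The histone genes H2bc23 and H4bc24 carried identical values in each library and cannot be counted as separate results. Their tested counts, with means of 5.92 in LKO and 33.2 in DKO, gave a 5.45-fold rise; the FPKM means, 0.453 and 6.35, lay further apart.

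The largest falls besides Aldh2 were of mixed kinds. NCBI gene 15101, which has no symbol in the annotation used, was at 1.94 ± 0.364 FPKM in LKO and 0.0067 ± 0.012 in DKO. Its counts were between 80.3 and 111 in the LKO libraries and at most 1.16 in the DKO libraries. It had no place in the gene order used, so its neighbours were not examined. A strain difference between the groups and an effect of ALDH2 loss cannot be told apart for this gene. Ctse, the aspartic protease cathepsin E, fell from 9.56 ± 0.937 to 0.517 ± 0.085 FPKM (log2 fold change −4.18 ± 0.18 SE, edgeR adjusted p = 3.33e-13). Chil1, a chitinase-like protein and a member of the neutrophil marker list, fell from 10.1 ± 0.211 to 2.15 ± 0.110 FPKM (log2 fold change −2.22 ± 0.13 SE). Lower levels were also found for Eps8l1 (0.970 to 0.080 FPKM), Chn2 (1.41 to 0.347), the small GTPase Rab38 (1.88 to 0.503) and Moap1 (0.790 to 0.240). The Moap1 call was lost in DESeq2 (adjusted p = 0.524), without LKO replicate 1 (0.0878) and without DKO replicate 1 (0.0636).

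**Figure D1:**
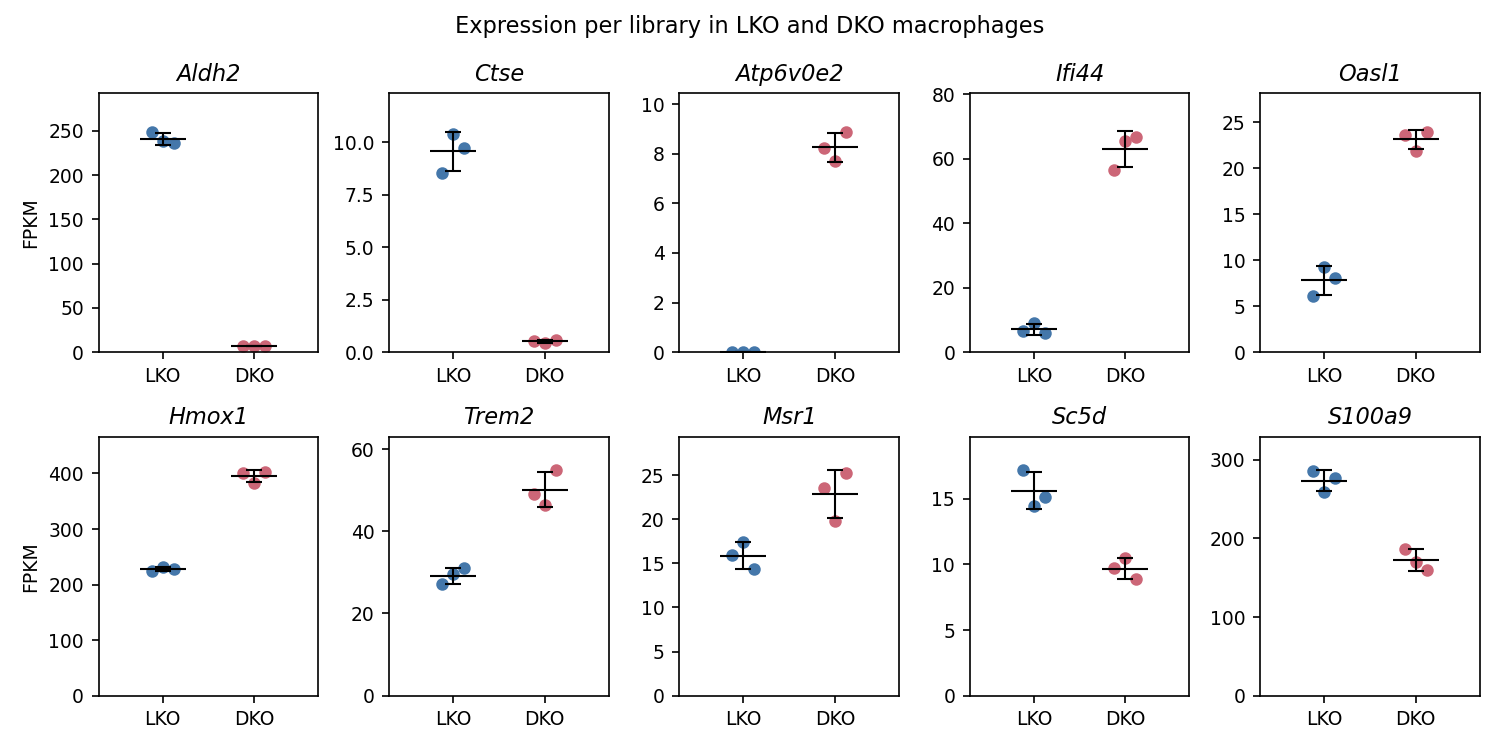
FPKM of 10 genes in each library (points) of LKO and DKO macrophages, with the mean (long bar) and SD (error bar) of 3 libraries per group; each vertical axis starts at 0. Aldh2 falls from 241 to 7.13 FPKM, Ctse falls from 9.56 to 0.517, Atp6v0e2 is at 0 in all LKO libraries, Ifi44, Oasl1, Hmox1, Trem2 and Msr1 are higher in DKO, and Sc5d and S100a9 are lower.

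Genes of the type I interferon response, which cells switch on against viruses, were broadly higher in DKO. Of 38 members tested, 33 rose, 1 fell and 4 did not pass; adjusted over the list alone, 34 rose and 1 fell. Besides Ifi44 and Ifi44l, the GTPase Iigp1 rose from 5.80 ± 0.662 to 17.6 ± 1.54 FPKM and Oasl1, an oligoadenylate synthetase-like protein, from 7.81 ± 1.60 to 23.1 ± 1.07. The member that fell was Gbp3, with a log2 fold change of −0.26. The list median was a log2 fold change of 0.56, also with Ifi44l set to its bound. The camera test gave an adjusted p of 2.45e-72 with its preset correlation and an adjusted p of 0.0942 with an estimated correlation, which ends the call. Among the 30 tested genes nearest to the deleted Aldh2, 4 changed by at least 1.5-fold, a number at the 95.6th percentile of all such windows: Oas3 (2.00-fold), Oas1g (1.69-fold) and Acad10 (1.71-fold) rose, and Adam1a fell 2.45-fold at low counts (means of 15.7 and 6.42; edgeR adjusted p = 0.0407).

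Genes of cholesterol synthesis were lower in DKO. Of 27 members tested, 18 fell and none rose (adjusted over the list alone, 20 fell and 1 rose), with a median log2 fold change of −0.33. Sc5d, a desaturase of late cholesterol synthesis, fell from 15.6 ± 1.40 to 9.66 ± 0.800 FPKM, Idi1 from 18.98 ± 1.80 to 12.8 ± 1.01 and Msmo1 from 42.4 ± 2.27 to 31.9 ± 1.75. The list passed camera (adjusted p = 4.93e-12) but not with an estimated correlation (adjusted p = 0.125). In fatty acid synthesis, 6 of 18 members fell and 3 rose (adjusted over the list alone, 8 and 3). The desaturase gene Scd2 fell from 34.2 ± 1.37 to 16.7 ± 3.25 FPKM and Fasn, the fatty acid synthase, from 9.08 ± 0.416 to 6.17 ± 0.270, while Acacb, Me1 (log2 fold change 1.21, not called by limma without a filter, adjusted p = 0.073) and Lpin1 (log2 fold change 0.21) rose. Camera called this list lower (adjusted p = 0.0269), the median log2 fold change was −0.11 and the mean was +0.01, so the mean differs in sign. Its call was lost with an estimated correlation (adjusted p = 0.242), on ranks (adjusted p = 0.084), in limma without a filter (adjusted p = 0.0607) and without LKO replicate 2 (adjusted p = 0.0559).

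Receptors for modified lipoproteins and immune complexes were higher in DKO. Of 19 tested members of the uptake and scavenger receptor list, 11 rose and none fell (adjusted over the list alone, 12 and none). The Fc receptor genes Fcgr3 and Fcgr1 rose from 165 ± 10 to 246 ± 27.2 FPKM and from 53.3 ± 3.41 to 75.8 ± 6.37. The scavenger receptor genes Scarf1 and Msr1 rose from 14.2 ± 1.13 to 20.8 ± 1.02 and from 15.9 ± 1.54 to 22.8 ± 2.76. Cd36, a major oxLDL receptor, did not pass, at 159 ± 11.3 FPKM in LKO and 151 ± 4.26 in DKO (edgeR adjusted p = 0.415). The list passed camera (adjusted p = 4.68e-07) but not with an estimated correlation (adjusted p = 0.0942).

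Lysosomal genes rose slightly. Of 51 tested hydrolases and membrane proteins, 17 rose and 3, among them Gusb and Cd63, fell (adjusted over the list alone, 20 and 3), with a median log2 fold change of 0.10. The cathepsin genes Ctsl and Ctsd rose from 138 ± 4.15 to 183 ± 6.77 FPKM and from 1907 ± 6.32 to 2364 ± 66.1. Mitf, a transcription factor of lysosomal genes, rose from 10.6 ± 0.732 to 14.3 ± 0.500 FPKM, and Lipa, the lysosomal acid lipase, from 214 ± 4.22 to 251 ± 6.52 (log2 fold change 0.24 ± 0.04 SE, edgeR adjusted p = 0.000165). Camera gave an adjusted p of 2.46e-05, and an adjusted p of 0.242 with an estimated correlation. The vacuolar proton pump subunits as a group did not pass camera (adjusted p = 0.436). Besides Atp6v0e2, Atp6v0d2 rose from 4.66 ± 0.497 to 6.40 ± 0.685 FPKM, while Atp6v1c1, Atp6v1b2 and Atp6v1e1 fell, and 15 of 20 subunits did not pass. The median of the pump subunits was −0.03 while the mean was positive, at +0.27 with Atp6v0e2 at its bound and −0.02 without it. The Atp6v0d2 call was lost in limma without a filter (adjusted p = 0.0932) and without DKO replicate 1 (0.0612). That of Atp6v1b2 was lost without LKO replicate 2 (edgeR adjusted p = 0.126), LKO replicate 3 (0.0526), DKO replicate 2 (0.113) or DKO replicate 3 (0.173). It was also lost in edgeR without a count filter (adjusted p = 0.0515) and in some limma fits (adjusted p up to 0.134).

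The other genes fixed in advance for cholesterol handling and regulation showed no change past the threshold. The cholesterol exporters Abca1 (39.0 ± 0.511 FPKM in LKO, 40.3 ± 0.945 in DKO, edgeR adjusted p = 0.414) and Abcg1 (7.11 ± 0.298 and 5.89 ± 1.17, edgeR adjusted p = 0.0763) did not pass. Abcg1 did pass without DKO replicate 2 (edgeR adjusted p = 0.0159). Npc1, the lysosomal cholesterol transporter, was at 47.2 ± 1.05 and 48.3 ± 0.690 FPKM (edgeR adjusted p = 0.565). The histone deacetylase gene Hdac3 was at 24.1 ± 0.402 and 24.3 ± 1.62 FPKM (edgeR adjusted p = 0.872), and Prkaa1, a catalytic subunit of the energy sensor AMPK, at 12.2 ± 0.344 and 12.6 ± 0.201 (edgeR adjusted p = 0.529). The list of cholesterol efflux and LXR target genes did not pass camera (adjusted p = 0.122), but did in edgeR without a count filter (camera adjusted p = 0.0463) and by fry's directional test (adjusted p = 0.0445). It had 4 members higher (Apoe, Nceh1, Cd5l and Apoc2), Lpl lower and 16 of 21 not passing. Apoe, the apolipoprotein that carries cholesterol out of macrophages, rose from 6256 ± 282 to 8719 ± 322 FPKM in edgeR (log2 fold change 0.49 ± 0.04 SE), but did not pass after quantile normalization (limma adjusted p = 0.509). The Cd5l call was lost in DESeq2 (adjusted p = 0.108) and in the limma fits.

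Oxidative stress genes under NRF2 were higher in DKO, with 14 of 29 tested members rising and 1, Slc7a11, falling (adjusted over the list alone, 17 and 2). Hmox1, the haem-degrading oxygenase, rose from 228 ± 3.18 to 396 ± 11 FPKM (log2 fold change 0.81 ± 0.04 SE, edgeR adjusted p = 7.95e-12). Gclm, a subunit of the enzyme that limits glutathione synthesis, rose from 22.3 ± 0.434 to 34.7 ± 2.57, Gstm1 from 39.4 ± 1.91 to 57.8 ± 2.88 and catalase (Cat) from 215 ± 4.58 to 258 ± 3.74. Metal handling genes rose in 7 of 13 members and fell in 1, Slc11a2 (adjusted over the list alone, 8 and 2), led by the iron exporter Slc40a1 (16.1 ± 0.806 to 31.8 ± 1.38 FPKM) and transferrin, Trf (105 ± 5.67 to 145 ± 21.7). The Trf call was lost in limma without a filter (adjusted p = 0.0684). Camera gave adjusted p = 9.78e-08 for the NRF2 list and 0.000262 for metal handling. With an estimated correlation neither passed (adjusted p = 0.114 and adjusted p = 0.15).

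Macrophage genes were higher in DKO as well. In the core macrophage list 13 of 25 members rose and 2, Cx3cr1 and Adgre1, fell (adjusted over the list alone, 13 and 3). Trem2, a lipid-sensing receptor, rose from 29.2 ± 1.94 to 50.1 ± 4.29 FPKM, Mertk, a receptor for dying cells, from 22.8 ± 0.497 to 31.6 ± 1.63, and Csf1r, the receptor for the macrophage growth factor, from 365 ± 21.4 to 484 ± 39.0. Alternative activation genes rose in 9 of 20 members and fell in 2, Gpnmb and Chil3 (adjusted over the list alone, 9 and 5). Folr2 rose from 54.1 ± 3.46 to 96.1 ± 1.59 FPKM and the mannose receptor Mrc1 from 105 ± 4.47 to 157 ± 14.9, while Gpnmb fell from 56.0 ± 2.73 to 29.3 ± 0.985. Of the 30 tested genes nearest to Csf1r, 6 changed by at least 1.5-fold, and 6 of those nearest to Gpnmb, against a median window of 1. Linked variants and an effect of ALDH2 loss on Csf1r or Gpnmb cannot be told apart. Extracellular matrix genes rose in 10 of 24 members and fell in 3, Col4a1, Mmp8 and Thbs1 (adjusted over the list alone, 13 and 5), with Spp1 going from 137 ± 4.30 to 201 ± 17.8 FPKM and Mmp9 from 43.3 ± 7.74 to 77.5 ± 14.8. Camera gave adjusted p = 1.72e-07, 0.037 and 5.92e-05 for these lists, and each lost its call with an estimated correlation (adjusted p = 0.242). The alternative activation call was also lost on ranks (adjusted p = 0.148), in limma without a filter (adjusted p = 0.0607) and without LKO replicate 1 (adjusted p = 0.0793). The markers of other cell types described next moved in the same libraries.

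Markers of other marrow cell types differed between the groups in both directions. Of 17 neutrophil markers tested, 10 fell and none rose in DKO (adjusted over the list alone, 12 fell), with a median log2 fold change of −0.61. Besides Chil1, the member with the smallest p, S100a9 fell from 274 ± 13.7 to 172 ± 13.6 FPKM, Ngp from 121 ± 5.60 to 78.7 ± 7.53 and S100a8 from 127 ± 13.6 to 80.0 ± 0.661. This list kept its call with an estimated correlation (camera adjusted p = 5e-13 preset, adjusted p = 0.0422 estimated). Of 9 lymphocyte markers 6 fell and none rose (adjusted over the list alone, 6 fell), including the B-cell genes Ms4a1 (3.17 ± 0.325 to 1.01 ± 0.284 FPKM), Cd79a (6.64 ± 1.68 to 2.66 ± 0.898) and Cd79b (96.0 ± 3.87 to 77.6 ± 2.23). Camera gave adjusted p = 0.000943 for lymphocyte markers, and adjusted p = 0.268 with an estimated correlation. The Cd79a call was lost in limma without a filter (adjusted p = 0.0573). Stromal and fibroblast markers moved the other way: 11 of 19 rose and none fell (adjusted over the list alone, 14 rose), with a median log2 fold change of 0.70. The collagen genes Col1a2 and Col1a1 rose from 10.7 ± 0.505 to 21.3 ± 3.13 FPKM and from 9.41 ± 1.26 to 18.6 ± 2.53, and Bgn from 10.8 ± 0.905 to 19.5 ± 3.22. Camera gave adjusted p = 2.75e-12 for this list, and adjusted p = 0.114 with an estimated correlation.

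Cell cycle genes were lower in DKO, where 16 of 40 fell and none rose (adjusted over the list alone, 22 fell). Top2a went from 9.87 ± 0.135 to 7.31 ± 0.309 FPKM, the proliferation marker Mki67 from 8.55 ± 0.373 to 6.53 ± 0.307 and the replication helicase gene Mcm5 from 9.14 ± 0.503 to 6.48 ± 0.503. Cytosolic ribosomal protein genes fell by small amounts, 30 of 38 with none rising (adjusted over the list alone, 37 fell) and a median log2 fold change of −0.18. Rpsa went from 648 ± 6.52 to 493 ± 16.7 FPKM and Rplp0 from 1149 ± 16.8 to 972 ± 34.8; these genes have many pseudogene copies and their counts can be shared. Camera gave adjusted p = 1.72e-07 and 3.57e-14, and with an estimated correlation adjusted p = 0.0942 and adjusted p = 0.242.

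In all, camera called 15 of the 34 lists tested, 9 higher and 6 lower, and 1 of them with an estimated correlation. These calls are at an adjusted p under 0.05. The 1.7 lists expected by chance at 0.05 apply to unadjusted p-values and are no measure for them. The other 9 ways of splitting the 6 libraries 3 against 3 also gave between 3 and 12 called lists with the preset correlation. Those splits mix the genotypes unevenly, so part of the genotype difference remains between their sides and their counts are no pure chance level. Among the lists that did not pass, autophagy had 4 higher members (Sqstm1, Ulk1, Ulk2 and Atg13), 1 lower (Optn) and 24 of 29 not passing (camera adjusted p = 0.0927). The autophagy list was called higher in 15 of 23 alternatives, with a range from 0.00743 to 0.295 over all of them. Among those 15 were limma on log2(FPKM + 1) (camera adjusted p = 0.0214) and edgeR without LKO replicate 1 (0.0412) or DKO replicate 2 (0.0452). The Ulk2 call was lost without LKO replicate 2 (edgeR adjusted p = 0.076), LKO replicate 3 (0.107), DKO replicate 2 (0.0667) or DKO replicate 3 (0.119), and in 9 of 10 limma fits. The limma fit without a filter also ended the calls of Ulk1 (adjusted p = 0.104) and Optn (0.0504). Fatty acid oxidation and lipid droplet genes had 5 higher, among them Cpt1a (9.47 ± 0.549 to 15.3 ± 1.55 FPKM), Plin2 (73.2 ± 0.917 to 92.2 ± 2.02), Acadm, Pnpla2 and Angptl4, and 1 lower, Pparg, of 24 (camera adjusted p = 0.139; fry's directional adjusted p = 0.00899). The Pnpla2 call was lost without LKO replicate 1 (edgeR adjusted p = 0.0553) or DKO replicate 1 (0.0578), and in all 10 limma fits (adjusted p up to 0.143). In the AMPK and mTORC1 list only Prkaa2 changed, downward, of 23 (camera adjusted p = 0.531), a call that DESeq2 did not make (adjusted p = 0.0698); Fnip1 passed, downward, without LKO replicate 3 (edgeR adjusted p = 0.0404). Among histone deacetylases and corepressors only Hdac9 changed, upward, of 21 (camera adjusted p = 0.882), a call lost in DESeq2 (adjusted p = 0.107) and without LKO replicate 2 (0.0544), LKO replicate 3 (0.109), DKO replicate 2 (0.051) or DKO replicate 3 (0.17), and in the 9 limma fits that held the gene. Sirt2 passed, downward, without LKO replicate 1 (edgeR adjusted p = 0.0255). Aldehyde and alcohol dehydrogenases and related reductases, Aldh2 kept apart, had 2 higher (Akr1b8 and Aldh3b1) and 3 lower (Akr1b10, Aldh6a1 and Akr1b3) of 17 (camera adjusted p = 0.373).

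**Figure D2:**
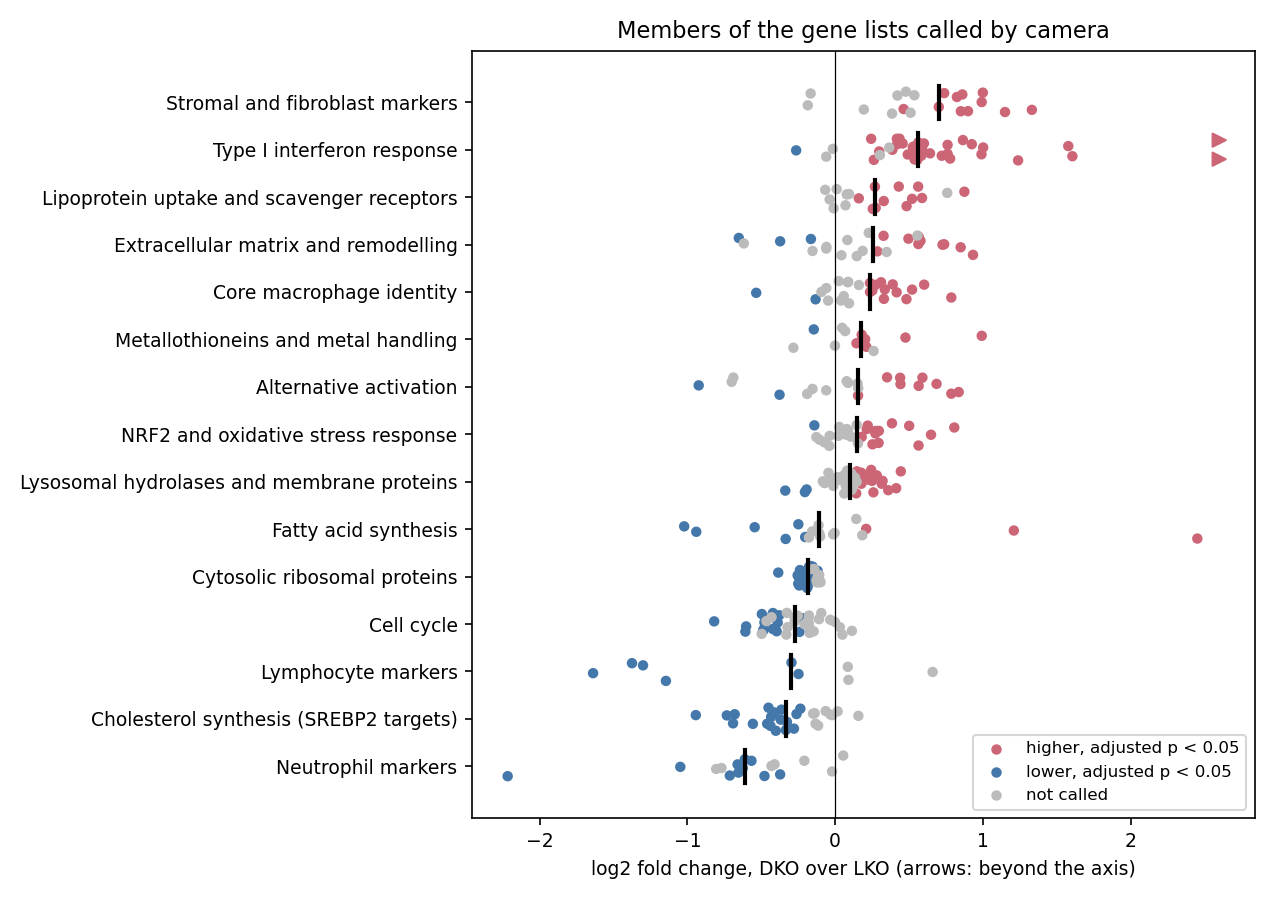
Log2 fold change (DKO over LKO, horizontal axis) of each tested member of the 15 gene lists called by camera, with vertical bars at the list medians; red and blue points passed an edgeR adjusted p of 0.05 upward and downward, and grey points did not. The medians run from −0.61 for neutrophil markers to 0.70 for stromal and fibroblast markers, and the 2 arrows in the interferon list stand for Ifi44 and Ifi44l, which lie beyond the axis.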

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

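Of the 149 genes that the naming rule takes and the 34 lists, none that passed turned its direction under an alternative; among all genes called by edgeR, 1 had the opposite sign in limma after quantile normalization. Aldh2 passed in each setting. The count of changed genes was 1687 with DESeq2 size factors, 1537 without a count filter, 1205 in DESeq2 and 1268 in limma with array weights. Leaving out 1 replicate gave between 1175 genes (without DKO replicate 3) and 1481, with between 625 and 753 higher and between 550 and 730 lower. Limma called 1130 genes (561 higher) with a pseudocount of 1, 1119 (557 higher) with 0.1, 1132 (563 higher) with 5, and 1147 (567 higher) after rescaling to TPM. It called 807 (425 higher, 382 lower) without a filter, 1076 (546 and 530) with an FPKM minimum of 5, 1108 (575 and 533) after quantile normalization, 1124 (571 higher) after median centring and 946 (475 and 471) without a variance trend. The FPKM minimum leaves fewer genes to test, 7777; for the other lower counts the cause was not tested. Requiring a log2 fold change of at least 1 left 144 genes (71 higher, 73 lower), and an adjusted p under 0.01 left 1005 (553 and 452), by the construction of those thresholds. Camera called between 14 and 19 lists in the alternative fits, 15 on ranks, 20 by fry and 1 with an estimated correlation, which allows for members that vary together. Why so few passed with it was not tested. In the neutrophil list the estimate was −0.04, below the preset 0.01, and the camera adjusted p still went from 5e-13 to 0.0422. Members that vary together therefore cannot account for that rise in p. The scavenger receptor and cell cycle lists had estimates of 0.027 and 0.029, near the preset, and still lost their calls. Of the 149 genes, DESeq2 kept 139 on their side of the threshold and limma without a filter 123.

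The replicate numbers shared by the groups do not pair the samples: same-numbered libraries correlated in their deviations from the group means by 0.02, −0.06 and −0.03, and other pairs across groups by −0.02 to 0.05. With the number as a replicate block, 1553 genes were called (810 higher, 743 lower) and 15 lists. The block brought Abcg1 past the threshold (edgeR adjusted p = 0.0463) and took Atp6v1b2 (0.0622) and Egr1 (0.0556) out of it, and moved no other of the 149 genes across it. At this depth, edgeR recovered 90% of simulated changes of 1.5-fold in well-counted genes, so smaller changes are missed more often. Recovery was not simulated for genes with few counts.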

Other observations

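Antigen presentation genes went both ways. Of 19 tested, 8 rose and 5 fell in DKO (adjusted over the list alone, 8 and 6), and the list did not pass camera (adjusted p = 0.223). It was called higher in DESeq2 (camera adjusted p = 0.0216), and the alternatives ranged from there to 0.57. No list per class was tested. Of the 8, the class I genes H2-D1 and H2-K1 rose from 1296 ± 64.2 to 1932 ± 45.5 FPKM and from 677 ± 24.9 to 993 ± 23.0; these are similar genes and their counts can be shared. The members that fell were the class II genes Cd74 (98.6 ± 6.49 to 53.7 ± 5.81 FPKM), H2-Eb1 (16.03 ± 0.878 to 7.56 ± 1.05), H2-Ab1 and H2-Aa, and their activator Ciita. The B-cell markers Ms4a1 and Cd79a and the dendritic cell marker Ccr7 fell in the same libraries. Inflammatory genes went both ways, with 6 of 24 higher and 4 lower (camera adjusted p = 0.373): Saa3 rose from 15.96 ± 5.86 to 46.0 ± 3.91 FPKM and Vcam1 from 1.11 ± 0.148 to 2.77 ± 0.083, while Lcn2 (32.9 ± 1.86 to 21.1 ± 1.05), the chemokine genes Ccl3 (56.4 ± 1.89 to 40.2 ± 2.14) and Ccl4, and Tnfaip3 fell. Among 28 chemokine and cytokine receptors 10 rose, and Cxcr4 (12.5 ± 1.03 to 4.74 ± 0.802 FPKM), Cx3cr1, Ccr7 and Tlr9 fell (camera adjusted p = 0.114). The receptor list was called higher in 13 of 23 alternatives, with a range from 0.00414 to 0.469 over all of them. In limma with a pseudocount of 1 the camera adjusted p was 0.0128. The osteoclast list had 3 members higher (Mmp9, Tnfrsf11a and Atp6v0d2) and the acid phosphatase Acp5 lower, from 171 ± 4.10 to 104 ± 5.32 FPKM (camera adjusted p = 0.544 over 6 members).

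The remaining lists did not pass camera in edgeR. The unfolded protein and integrated stress list had 8 of 30 members lower, including Herpud1 (178 ± 2.26 to 135 ± 2.77 FPKM), and Atf5 and Edem1 higher (adjusted p = 0.257; fry's directional adjusted p = 0.0401). Apoptosis and p53 targets had 4 of 27 higher (Zmat3, Cdkn1a, Bak1 and Bbc3) and 3 lower (Pmaip1, Bcl2 and Casp1; adjusted p = 0.147, 0.0467 without DKO replicate 3, and 0.0254 in limma with an FPKM minimum of 5). Glycolysis and hypoxia genes had P4ha1 higher and Ndrg1 (657 ± 10.8 to 510 ± 10.1 FPKM) and Hk2 lower of 31 (adjusted p = 0.207; 0.0314 in limma with array weights); Car9 passed, downward, in 2 limma fits and without LKO replicate 3 (adjusted p from 0.0368 to 0.0476). In oxidative phosphorylation only Atp5o passed, downward, of 37 (adjusted p = 0.332). Atp5g1 passed, downward, in 4 limma fits and without LKO replicate 1 or DKO replicate 1 (adjusted p from 0.0255 to 0.0435), Atp5b in limma with array weights (0.049) and Cox4i1 without DKO replicate 1 (0.047), both downward. Immediate early and heat shock genes had 4 of 20 higher (Junb, Egr1, Egr2 and Ier3) and Atf3 and Hspa8 lower (adjusted p = 0.528). Dendritic cell markers had Bst2 higher and Ccr7, Ciita and Fscn1 lower of 9 (adjusted p = 0.419), erythroid and megakaryocyte markers Pf4 and Tfrc higher of 7 (adjusted p = 0.44; fry's directional adjusted p = 0.0117), and replication-dependent histones H1f2 higher of 6 (adjusted p = 0.373). Gp9, of the erythroid and megakaryocyte list, passed, downward, in 7 limma fits (adjusted p from 0.0294 to 0.047) and without LKO replicate 2 (0.0403), as did the histone gene H2bc4 without LKO replicate 2 (0.0328). Leaving out a single library ended some of these gene calls (edgeR adjusted p in brackets). Without LKO replicate 1 this was Egr1 (0.113), and without LKO replicate 2 it was Hk2 (0.0684), Atp5o (0.076), Egr1 (0.152), Ciita (0.104), Tfrc (0.0997) and H1f2 (0.0787). Without LKO replicate 3 it was Hk2 (0.0962), Ccr7 (0.0744), Ciita (0.0698), Fscn1 (0.21) and Tfrc (0.123), and without DKO replicate 1 Hk2 (0.0918), Egr1 (0.0511), Ccr7 (0.0606), Fscn1 (0.128) and Tfrc (0.113). Without DKO replicate 2 it was Hk2 (0.105), Atp5o (0.117), Egr1 (0.24), Ciita (0.132), Fscn1 (0.0945) and H1f2 (0.0828), and without DKO replicate 3 Ccr7 (0.0671), Fscn1 (0.0696), Tfrc (0.135) and H1f2 (0.0699). DESeq2 did not call Hk2 (adjusted p = 0.0671), Egr1 (0.136), Ciita (0.0926), Fscn1 (0.159), Tfrc (0.0678) and H1f2 (0.093). At least 1 limma fit did not call these genes, nor Atp5o, Ccr7, Cd79a and Atp6v0d2, nor Bak1 (adjusted p from 0.0501 to 0.125), Pmaip1 (0.0599), Junb (up to 0.0781) and Hspa8 (up to 0.152), and edgeR without a count filter did not call Egr1 (0.0606) and Fscn1 (0.0504).

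Some abundant or strain-related genes outside the lists also changed and were chosen after their values were seen. Slc13a3, a dicarboxylate transporter, fell from 2625 ± 68.5 to 1588 ± 41.5 FPKM (edgeR adjusted p = 4.12e-12). Nnt, the mitochondrial transhydrogenase that is truncated in the C57BL/6J substrain, was at 14.8 ± 0.379 FPKM in LKO and 21.9 ± 0.795 in DKO (edgeR adjusted p = 1.86e-09). Its mean counts were 687 in LKO and 1156 in DKO, so it was counted in both groups. The fitted rise in counts was 1.68-fold, but the FPKM means lay closer together, so the length used for scaling was longer in DKO. Which form of Nnt a group carried was not examined, so a substrain difference between the groups was not tested and stays open.

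Of the tests on the 3 patterns below, those of neighbouring genes and of the paralog for Atp6v0e2, of the stromal markers, and of the interferon list without Ifi44 and Ifi44l were chosen after the result was seen.

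The first pattern is the appearance of Atp6v0e2, counted at 0 in LKO, together with changes in genes beside it. Reads shared with the paralog Atp6v0e are argued against, since its mean count rose by 98.3 in DKO while Atp6v0e2 gained 167 and its counts were whole. Strain variants that travel with a knockout or a breeding line could alter several neighbouring genes: 5 of the 30 nearest tested genes (Zfp862-ps, Gimap4, Gimap6, Gpnmb and Igf2bp3) changed by at least 1.5-fold, at the 98.1th percentile of windows, and 1.01 would be expected. Without the Gimap genes, which are mostly lymphocyte genes, the count is 3, at the 89.3th percentile. A window of 5 is found somewhere in 992 of 1000 shuffled gene orders, while the highest window of 8, around Cycs and Hnrnpa2b1 nearby in gene order, was reached in 7 of them. Linked variants and an effect of ALDH2 loss on Atp6v0e2 itself therefore cannot be told apart with these libraries, because the labels do not give how the lines were bred.

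The second pattern is the lower level of neutrophil and B-lineage genes. A lower share of all cells other than macrophages in DKO is argued against by the stromal and fibroblast markers, whose median log2 fold change was 0.70. Further neutrophil-lineage genes, fixed before they were looked at, had a median log2 fold change of −0.45 with 2 of 6 lower, which is consistent with fewer neutrophil-lineage cells in DKO; the most abundant marker, S100a9, stood at 274 and 172 FPKM, and 4 of the 20 neutrophil genes in the files are in other lists too. Further B-lineage genes had a median of −0.45 with 3 of 10 lower, which lies between the bounds set for and against. The bound set in advance for fewer cells was stricter for the B lineage than for the neutrophil lineage. As the medians were alike, the different outcomes come from the bounds and do not separate the lineages. For the B lineage, fewer cells and lower expression within cells cannot be told apart. An effect of genotype on expression in the macrophages themselves stays open, as untested.

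The third pattern is the rise of interferon response genes. That it rests on Ifi44 and Ifi44l alone is argued against, since the mean log2 fold change of the other 36 members was 0.59 ± 0.06 SE, against 0.84 for the list with Ifi44l at its bound. Variants at a few linked loci that act only on the genes next to them are argued against as the source of the whole list's rise. The 33 members that rose lie on 15 chromosomes, a spread that follows once so many members rise. It cannot speak to a variant that acts on interferon genes at a distance, which stays open. Nor can it speak to single genes such as Oas3 and Oas1g beside Aldh2. Transcript length and expression level are argued against as well, since the highest median among 10000 random lists matched on both was 0.11 and 0 of them reached the list's 0.56. An effect of ALDH2 loss on interferon signalling stays open as an untested hypothesis, and so does a difference between cultures or animals.

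The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 1689 changed genes in edgeR and was the highest, as 1 of 10, while the highest of the other 9 gave 0 (between 161 and 389 genes at an unadjusted p under 0.05, and between 0 and 2 in DESeq2). For gene lists, the real split gave 15 and the highest other split 12, again with 1 of 10 splits reaching the real value. Each of the other 9 splits holds both genotypes on each side, in uneven shares. The genotype difference then widens the spread within sides, so few called genes were bound to follow and they measure no false-call rate. Part of that difference also remains between the sides, so the lists called there are no pure chance level.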
